A study of Mus musculus with 12 samples.

How the data were processed

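RNA sequencing was used to profile HSCs sorted from mouse bone marrow in 12 libraries, 3 each from control mice, antibiotic-treated mice, and both kinds of mice on day 12 after 5-FU. Per the labels, total RNA of 2000 sorted cells was extracted with the RNeasy Plus Micro kit, and libraries were made with SMART-Seq v4, which primes on poly(A) tails, and Nextera XT. The sort gates are not given in the sources used here. The submitters' processing notes name STAR 2.5.3a, Partek and the mm10 build. The counting rule, the strand setting and the annotation release are not given in the sources used here.

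The deposited table gives RPKM made by the authors for 46986 features in the 12 libraries, and every column was used. The value 0.0001 stands in place of 0, and 26832 features lie above it in at least 1 library. The values sum to between 142127 and 176924 per library and were not scaled to a common total. Pseudogenes make up 9371 features, of which 982 passed the filter, and reads shared with other loci make their values uncertain. A symbol is on more than 1 feature for 15 symbols and 42 features, which were kept apart. Coordinates and biotypes were taken from the table. GENCODE M21, which may differ from the release the authors used, gave transcript lengths and sequences and a check of the coordinates. Of 44007 genes matched to that annotation by symbol, 88.1% had the same start, and 87.9% had a stop 1 base past the annotated end, so the end is given as the stop less 1. The transcripts of 5 abundant nuclear pseudogenes were aligned to the mitochondrial genes with BLAST+ 2.17.0 and matched at 97.605% to 100%.

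Total read counts are not stated, so relative depth was estimated from the steps between low values. Within a library, a value of 1 read sets the step of a gene, and the estimate used 2403 to 2925 low genes per library with 0.5 to 10.5 steps. Between 48.8% and 54.2% of their values lay within 2% of a whole number of steps, too few to recover reads, so no count test was run. The estimates range from 27.9 to 54.8 M reads. They limit precision for genes at a few RPKM, where the spread between libraries includes counting error.

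Values were analysed as log2(RPKM + 1) for the 8553 genes with at least 1 RPKM in at least 3 libraries. With R 4.3.3 and limma 3.58.1, all 12 libraries were fitted in 1 model with 4 group means and 8 residual degrees of freedom, with empirical Bayes moderation along an intensity trend (prior degrees of freedom 3.34), two-sided tests and Benjamini-Hochberg adjustment within each comparison, called at 0.05. The comparisons were antibiotics against control at steady state, 5-FU against none without and with antibiotics, antibiotics against control after 5-FU, and the interaction. A single gene compared alone by an exact permutation test of 3 against 3 could not reach a p below 0.1, so none was run. Groups that did not overlap had all 3 libraries of one group above all 3 of the other.

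Gene lists were fixed before the data were examined: 30 lists with 870 entries. They cover HSC identity, quiescence regulators, S phase, G2/M phase, iron uptake, storage and export, mitochondrial iron-sulfur and heme synthesis, fatty acid oxidation, oxidative phosphorylation, glycolysis, type I interferon, interferon gamma, MHC class II, NF-kB and TNF, immediate early and dissociation response, ribosome biogenesis and MYC targets, p53 targets, antioxidant and ferroptosis genes, the unfolded protein response, and autophagy and lysosome. The others cover myeloid progenitors, mature neutrophils and monocytes, erythroid, megakaryocyte and platelet, lymphoid progenitors, B cells, T and NK cells, macrophages, stroma and endothelium, basophils and mast cells, and mitochondrially encoded transcripts. Symbols missing from the table were Flvcr1, Flvcr2, Ahsp, Hbb-b1 and Hbb-b2, and Fdx2 is listed as Fdx1l. The 25 lists with at least 5 measured members were tested with camera in limma at a preset correlation between genes of 0.01, which compares a list with the other genes. Camera was repeated with a correlation estimated from the residuals. The rotation test fry, which asks whether a list moves on balance one way without comparing it with other genes, was run as a further description and is not used for calls. List calls were adjusted over the 25 lists.

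Named genes were chosen by a rule fixed before the data were examined. In each pairwise comparison it takes up to 8 higher and 8 lower called genes by absolute log2 change, with a mean of at least 5 RPKM in the higher group and no overlap between the groups, without predicted or mitochondrial genes, filled to 4 by the smallest p. It adds up to 4 members with the smallest p of each list that was called or held a called gene, for the interaction up to 6 genes per direction filled to 4, and Tfrc, Fth1, Slc40a1, Hlf, Mecom, Procr, Mki67 and Cdkn1a everywhere. Gm5537, Snn, Gm37599, Lyz2 and the mitochondrial pseudogenes are named outside the rule, after their values were seen. Principal components were computed from the centred log2 values of the 8553 genes. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

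Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a filter at 5 RPKM, RPKM converted to TPM by giving each library the same sum, quantile normalization, a fit of only the 6 libraries compared, robust moderation, library weights, the i7 index as a block for the antibiotic comparisons, an estimated correlation for lists, and leaving out each library in turn. Values rescaled to one total, protein-coding genes alone and the estimated depth as a covariate were added after the data had been seen. The methods were tested on simulated data in which 200 of 8553 genes changed by 0.5, 1 or 2 on the log2 scale. Per comparison, 43.9% to 73.8%, 81.0% to 97.0% and 97.0% to 100% of these were recovered in that order. Of unchanged genes 10 to 22 were called, and 0 with no change. All 4 lists shifted by 0.3 were always recovered with 0 false lists, but splits of real libraries called up to 14.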

Results

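RNA was measured in hematopoietic stem cells (HSCs) sorted from the bone marrow of 12-week-old C57BL/6 mice. The 12 libraries fall into 4 groups of 3: control, antibiotics, control 5-FU and antibiotics 5-FU. Antibiotic-treated mice drank ampicillin, neomycin, metronidazole and vancomycin for 4 to 6 weeks, a mixture used to deplete gut bacteria, which were not measured here. The antimetabolite 5-fluorouracil (5-FU), given once into a vein at 200 mg/kg, kills dividing marrow cells, and the 5-FU libraries were taken on day 12 of recovery. Each library came from RNA of 2000 sorted cells. The labels do not say whether the libraries of a group come from separate animals, so p-values measure only the spread between these libraries. Unless stated otherwise, expression is given as mean ± SD in RPKM over n = 3 libraries, log2 changes are given ± SE, also in parentheses after a gene name, list medians are of log2 changes, and positions refer to mm10.

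The read depth estimated from the steps between low values was 50.4 ± 5.51 M reads in control, 32.7 ± 4.59 M with antibiotics, 41.2 ± 13.1 M in control 5-FU and 35.1 ± 3.41 M in antibiotics 5-FU libraries (SD, n = 3). At steady state the antibiotic libraries, 29.2 to 37.9 M, did not overlap the control libraries, 44.2 to 54.8 M. The summed RPKM was lower after 5-FU, 149253 ± 6172 against 169263 ± 4633 without antibiotics and 153338 ± 3628 against 173185 ± 6347 with antibiotics. Pseudogenes held 41.2% to 46.0% of the summed RPKM, and the 20 highest features held 20.7% to 24.8%. None of the 37 genes of the mitochondrial chromosome rose above the floor of the table, while nuclear pseudogenes with the same sequence did. Gm28437 (chromosome 1, 24613189 to 24613971), identical to mt-Co3 over 783 nt, reached 4338.3 to 6466.3 RPKM. The titles name 1 flow cell for all 12 libraries. Libraries with and without 5-FU carried different i7 indexes, so an effect of the index cannot be told apart from 5-FU, whereas each index was shared by 1 library with and 1 without antibiotics.

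5-FU separated the libraries along the first principal component, which held 44.3% of the variance, with values from -19.98 to -11.12 without 5-FU and from 12.79 to 18.3 with 5-FU. The second component held 14.7% and the third 13.4%. Pearson correlations across genes between libraries of a group were 0.987 to 0.993 for control, 0.985 to 0.989 for antibiotics and 0.985 to 0.990 for antibiotics 5-FU. Control 5-FU replicate 1 stood apart on the third component at 23.58 and had correlations of 0.971 and 0.972 with the other libraries of its group, against 0.989 between those. It correlated at 0.981 with antibiotic 5-FU replicate 1, which shares its i7 index and came next on that component at 7.73.

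**Figure D1:**
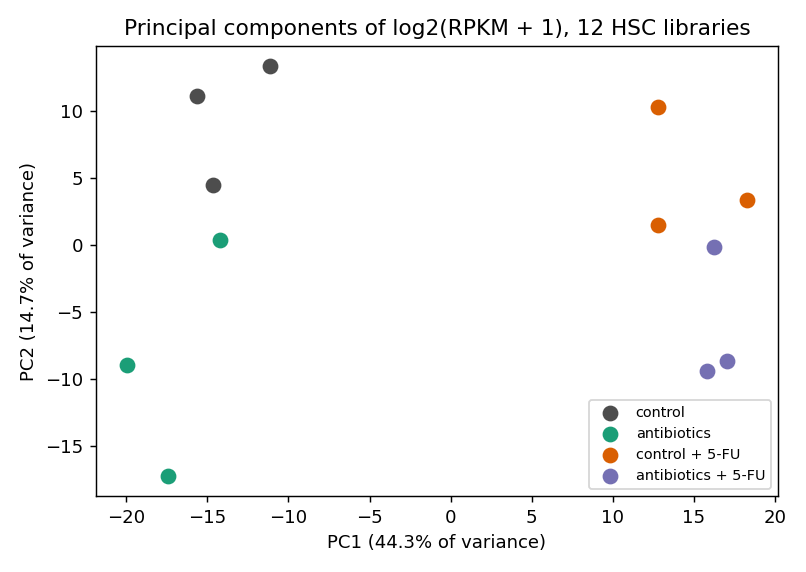
Principal components of the 12 libraries from log2(RPKM + 1) of 8553 genes, with each point 1 library, colours for the 4 groups and the share of variance on each axis. The 6 libraries after 5-FU lie at 12.79 to 18.3 on the first component and the 6 others at -19.98 to -11.12.

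The comparison of control 5-FU with control asked how HSCs regenerating on day 12 differed from HSCs at steady state in mice that had no antibiotics. Genes of DNA replication, mitosis, ribosome biogenesis and respiration were lower on day 12, and genes of NF-kB signalling, of HSC identity and of the megakaryocyte branch were higher. Of these lists, NF-kB alone also passed with an estimated correlation. Wfdc17 (chromosome 11, 83703991 to 83706268), which encodes a small secreted protein with a whey acidic protein domain, rose from 1.86 ± 0.379 to 84.3 ± 28.7 RPKM, a log2 change of 4.84 ± 0.24 (adjusted p = 1.33e-06). Socs3 (chromosome 11, 117966079 to 117970047), a feedback inhibitor of cytokine receptors, rose from 3.45 ± 0.665 to 32.1 ± 8.49 RPKM, a log2 change of 2.87 ± 0.17 (adjusted p = 5.18e-06). Serpinf1 (chromosome 11, 75409769 to 75422701), which encodes a secreted serpin, fell from 12.3 ± 1.59 to 2.19 ± 0.0582 RPKM, a log2 change of -2.05 ± 0.097 (adjusted p = 1.33e-06). Of 8553 genes tested with limma, 1846 passed an adjusted p of 0.05, 833 higher and 1013 lower, and 3127 had an unadjusted p under 0.05. Among the called genes, 69 were at least 2-fold higher and 39 at least 2-fold lower on the log2(RPKM + 1) scale, which understates the change of genes with low values. The libraries of the pair of groups did not overlap for 37.0% of genes, against 10% by chance.

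Among the strongest increases were Cd53 (2.76 ± 0.17, adjusted p = 5.8e-06), a leukocyte tetraspanin, Il10ra (2.53 ± 0.18, adjusted p = 2.06e-05), a chain of the interleukin-10 receptor, and Cebpd (2.16 ± 0.28, adjusted p = 0.000973), a transcription factor of myeloid genes. The neutrophil genes S100a8 (2.70 ± 0.58, adjusted p = 0.00893), S100a9 (2.36 ± 0.54, adjusted p = 0.012) and Ngp (2.20 ± 0.72, adjusted p = 0.0498) were among them too. Their values in control 5-FU replicates 1, 2 and 3 were 21.4, 57.7 and 143 RPKM for S100a8, against 5.22 to 10.96 RPKM in control libraries. Among the strongest decreases were Myl10 (-2.81 ± 0.45, adjusted p = 0.00229), a myosin light chain, Thbs1 (-2.15 ± 0.48, adjusted p = 0.0111), the adhesive glycoprotein thrombospondin-1, and Tcf19 (-1.50 ± 0.21, adjusted p = 0.00124), which peaks in expression at the start of S phase. The alpha-tubulin Tuba1b fell from 628 ± 74.8 to 261 ± 30.2 RPKM, a log2 change of -1.26 ± 0.12 (adjusted p = 0.000163). Ngp lost its call in 11 of the 12 fits that left out 1 library, with adjusted p = 0.15 without control replicate 1 and 0.0226 to 0.17 over the other alternatives, and its log2 change was 1.22 without control 5-FU replicate 3. With no filter on low values S100a9, Ngp and Thbs1 were not called.

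In the S phase list 37 of 45 measured members fell and 0 rose (38 and 0 adjusted over the list alone). The S phase median was -0.65 (adjusted p = 1.91e-15, alternatives from 1.46e-25 to adjusted p = 0.405 with an estimated correlation). The helicase subunit Mcm7 fell from 44.1 ± 5.55 to 22.1 ± 2.42 RPKM, a log2 change of -0.96 ± 0.11 (adjusted p = 0.000524), and Uhrf1 (-1.21 ± 0.15, adjusted p = 0.000779), which couples replication to DNA methylation, fell with it. In the G2/M list 19 of 47 measured members fell and 0 rose (28 and 0 adjusted over the list alone). The G2/M median was -0.42 (adjusted p = 2.83e-08, alternatives from 2.76e-13 to adjusted p = 0.405 with an estimated correlation). Its members Tubb4b (-0.88 ± 0.10, adjusted p = 0.000539) and Cks1b (-1.17 ± 0.16, adjusted p = 0.00124) fell. In the list of ribosome biogenesis and MYC targets 18 of 43 measured members fell and 0 rose (22 and 0 adjusted over the list alone). The ribosome biogenesis median was -0.26 (adjusted p = 5.31e-07, alternatives from 2.05e-11 to adjusted p = 0.405 with an estimated correlation). Myc itself fell from 69.4 ± 5.67 to 37.8 ± 7.32 RPKM, a log2 change of -0.87 ± 0.13 (adjusted p = 0.00194), with the small nucleolar ribonucleoprotein genes Fbl (-0.49 ± 0.079, adjusted p = 0.00251) and Nop56 (-0.56 ± 0.093, adjusted p = 0.00293).

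In the oxidative phosphorylation list 16 of 58 measured members fell and 0 rose (26 and 0 adjusted over the list alone). The oxidative phosphorylation median was -0.27 (adjusted p = 3.85e-09, alternatives from 1.99e-16 to adjusted p = 0.405 with an estimated correlation). It was -0.18 without control 5-FU replicate 3. Ndufa4 (-0.63 ± 0.11, adjusted p = 0.00396) and Cox6b1 (-0.43 ± 0.098, adjusted p = 0.0114), subunits of the respiratory chain, were 2 of them. In the glycolysis list 5 of 19 measured members fell and 0 rose (6 and 0 adjusted over the list alone). The glycolysis median was -0.11 (adjusted p = 0.0437, alternatives from 0.0184 to adjusted p = 0.405 with an estimated correlation, not called in 7 of 11 alternatives). It was -0.21 without control 5-FU replicate 1 and -0.061 without control 5-FU replicate 2. The enzymes Tpi1 (-0.62 ± 0.11, adjusted p = 0.00337) and Gapdh (-0.45 ± 0.10, adjusted p = 0.0113) fell. The glycolysis median turned from -0.11 to 0.044 when values were converted to TPM and to 0.042 when rescaled to one total, where the list was not called. The list also lost its call without control replicate 2, control replicate 3 or control 5-FU replicate 2, with adjusted p = 0.111 without control 5-FU replicate 2. Because the summed RPKM was lower after 5-FU, converting to TPM moved the median log2 change of all genes from 0.005 to 0.177 and the share of called genes that were higher from 45.1% to 81.1%.

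In the NF-kB list 11 of 19 measured members rose and 0 fell (12 and 0 adjusted over the list alone). The NF-kB median was 0.42 (adjusted p = 6.81e-07, alternatives from 8.55e-09 to adjusted p = 0.0135 with an estimated correlation). The subunit Nfkb1 (0.55 ± 0.069, adjusted p = 0.000779), the inhibitor Nfkbia (0.75 ± 0.13, adjusted p = 0.00368) and the chemokine Ccl4 (1.08 ± 0.16, adjusted p = 0.00151) rose. In the immediate early list, which also marks cell dissociation, 5 of 19 measured members rose and 1 fell (6 and 1 adjusted over the list alone). The immediate early median was 0.50 (adjusted p = 0.0152, alternatives from 0.00181 to adjusted p = 0.405 with an estimated correlation, not called in 4 of 11 alternatives). The AP-1 factor Junb (1.23 ± 0.17, adjusted p = 0.0012) rose. In the list of p53 targets 7 of 18 measured members rose and 0 fell (8 and 1 adjusted over the list alone). The p53 target median was 0.29 (adjusted p = 0.00671, alternatives from 5.04e-05 to adjusted p = 0.132 with an estimated correlation). The antiproliferative gene Btg2, which this list shares with the lists of quiescence regulators and immediate early genes, rose from 3.46 ± 0.745 to 12.7 ± 4.48 RPKM, a log2 change of 1.58 ± 0.25 (adjusted p = 0.00216). In the autophagy and lysosome list 5 of 25 measured members rose and 0 fell (5 and 0 adjusted over the list alone). The autophagy median was 0.19 (adjusted p = 0.000556, alternatives from 4.33e-05 to adjusted p = 0.215 with an estimated correlation). The lysosomal membrane gene Lamp2 (0.67 ± 0.078, adjusted p = 0.000585) and the autophagy receptor Sqstm1 (0.43 ± 0.091, adjusted p = 0.00864) rose.

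In the HSC identity list 10 of 24 measured members rose and 1 fell (11 and 2 adjusted over the list alone). The HSC identity median was 0.25 (adjusted p = 0.00934, alternatives from 0.000271 to adjusted p = 0.405 with an estimated correlation). It was 0.16 without control 5-FU replicate 3. Hoxb5 (0.70 ± 0.099, adjusted p = 0.00138), a marker of long-term HSCs, and Ly6a (1.03 ± 0.16, adjusted p = 0.00216), which encodes Sca-1, rose. In the list of quiescence regulators 5 of 14 measured members rose and 1 fell (7 and 1 adjusted over the list alone). The quiescence median was 0.42 (adjusted p = 0.00682, alternatives from 6.36e-05 to adjusted p = 0.215 with an estimated correlation, not called in 3 of 11 alternatives). Its member Tgfbr2 (0.49 ± 0.070, adjusted p = 0.00138) rose and Ndn (-0.88 ± 0.13, adjusted p = 0.00147) fell. In the megakaryocyte and platelet list 13 of 22 measured members rose and 3 fell (13 and 3 adjusted over the list alone). The megakaryocyte median was 0.64 (adjusted p = 0.00109, alternatives from 5.61e-05 to adjusted p = 0.405 with an estimated correlation). P-selectin, encoded by Selp, rose from 3.04 ± 1.14 to 14.8 ± 0.721 RPKM, a log2 change of 2.01 ± 0.17 (adjusted p = 6.39e-05), and Plek (0.79 ± 0.15, adjusted p = 0.00502) rose with it. The HSC identity list lost its call without control replicate 1 (adjusted p = 0.0533).

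In the list of myeloid progenitor genes 3 of 10 measured members rose and 1 fell (4 and 1 adjusted over the list alone). The myeloid progenitor median was 0.33 (adjusted p = 0.0164, alternatives from 6.45e-05 to adjusted p = 0.224 with an estimated correlation, not called in 3 of 11 alternatives). Its member Plac8 (1.23 ± 0.17, adjusted p = 0.00117) rose. In the lymphoid progenitor list 4 of 12 measured members rose and 0 fell (4 and 0 adjusted over the list alone). The lymphoid progenitor median was 0.18 (adjusted p = 0.0106, alternatives from 0.00233 to adjusted p = 0.405 with an estimated correlation). It was 0.29 without control 5-FU replicate 1 and 0.12 without control 5-FU replicate 3. In the list of mature neutrophil and monocyte markers 4 of 7 measured members rose and 0 fell (5 and 1 adjusted over the list alone). The neutrophil marker median was 1.29 (adjusted p = 0.018, alternatives from 0.00126 to adjusted p = 0.405 with an estimated correlation, not called in 4 of 10 alternatives). It was 0.85 without control 5-FU replicate 3 and 0.27 with no filter. This list lost its call without control replicate 1 or control 5-FU replicate 2, with adjusted p = 0.0879 without control replicate 1. Its member S100a6 rose from 2.85 ± 0.175 to 5.91 ± 0.0863 RPKM, a log2 change of 0.84 ± 0.10 (adjusted p = 0.000645). The abundant member Lyz2 stood at 115 ± 4.72 RPKM without and 112 ± 14.1 RPKM with 5-FU. The mean log2 value of the members set all 3 control 5-FU libraries apart from all 3 control libraries in each called list except oxidative phosphorylation.

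The remaining lists did not pass the test without antibiotics. In the type I interferon list 3 of 33 measured members rose and 1 fell (3 and 1 adjusted over the list alone) with a median of 0.018 (adjusted p = 0.493), and in the interferon gamma list 6 of 31 measured members fell and 4 rose (7 and 4 adjusted over the list alone) with a median of 0.006 (adjusted p = 0.824). In the fatty acid oxidation list 4 of 30 measured members fell and 2 rose (4 and 2 adjusted over the list alone), with a median of -0.056 (adjusted p = 0.547). The iron list had a median of -0.047 (adjusted p = 0.831). Medians were -0.059 (adjusted p = 0.453) for iron-sulfur and heme synthesis, -0.42 (adjusted p = 0.228) for MHC class II, -0.085 (adjusted p = 0.466) for antioxidant genes and -0.031 (adjusted p = 0.453) for the unfolded protein response. They were 0.60 (adjusted p = 0.493) for erythroid genes, of which 2 of 15 rose, the globin Hbb-bt (2.07 ± 0.40, adjusted p = 0.00586) among them, and 1, Car2 (-0.77 ± 0.11, adjusted p = 0.00124), fell (2 and 1 adjusted over the list alone). The median was 0.038 (adjusted p = 0.493) for macrophage markers, of which Apoe (0.64 ± 0.12, adjusted p = 0.00423) rose. Median, mean and test differed in sign for the iron list (-0.047, 0.004, up) and the interferon gamma list (0.006, 0.086, down). Lists with fewer than 5 measured members were not tested. Their medians were 0.36 for B cell, 1.06 for T and NK cell and -0.021 for stromal and endothelial markers and 0.08 for the basophil and mast cell branch, and no mitochondrially encoded transcript was measured. Among them, the NK receptor gene Klrb1c (1.78 ± 0.14, adjusted p = 3.54e-05) and the endothelial gene Pecam1 (0.69 ± 0.13, adjusted p = 0.00502) rose.

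**Figure D2:**
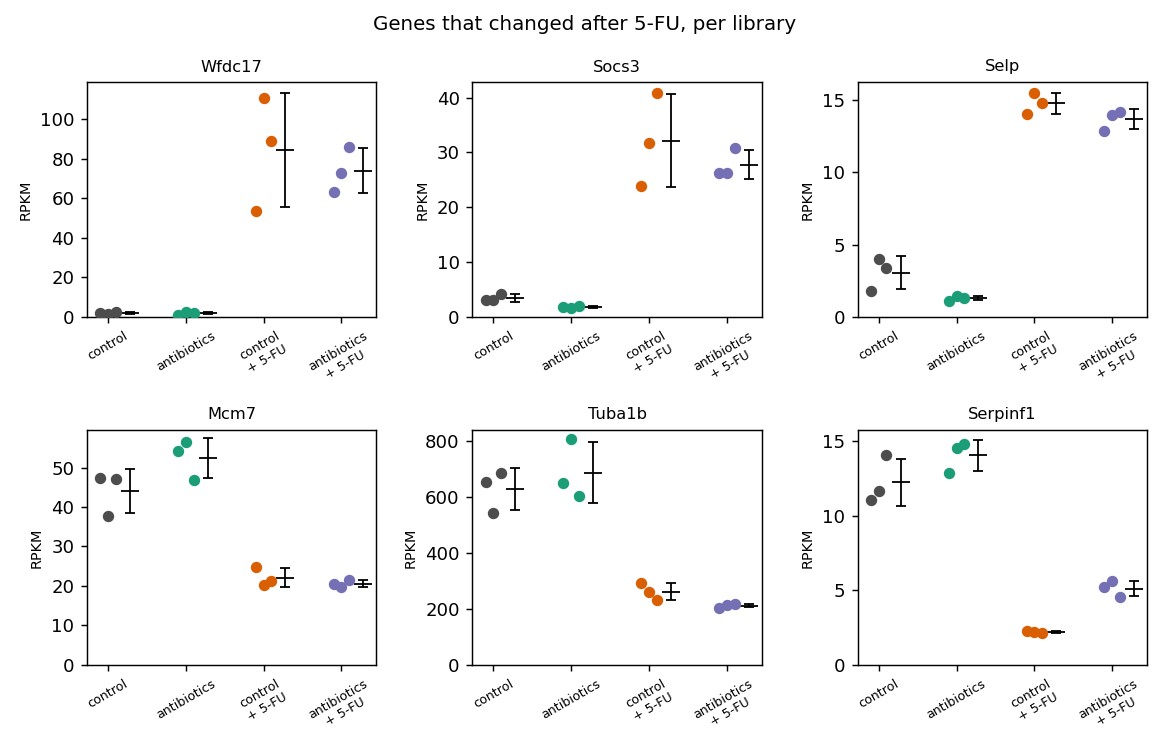
RPKM of Wfdc17, Socs3, Selp, Mcm7, Tuba1b and Serpinf1 in the 4 groups, with points for the 3 libraries of each group and a dash with a bar for mean ± SD. Wfdc17, Socs3 and Selp are higher and Mcm7, Tuba1b and Serpinf1 lower after 5-FU, both without and with antibiotics.

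The same comparison in antibiotic-treated mice asked how HSCs differed on day 12 after that treatment. Replication, mitosis and ribosome biogenesis genes were again lower, and NF-kB, HSC identity, type I interferon and fatty acid oxidation genes were higher, of which NF-kB alone also passed with an estimated correlation. Wfdc17 rose from 1.84 ± 0.599 to 73.9 ± 11.3 RPKM, a log2 change of 4.74 ± 0.24 (adjusted p = 1.71e-06). Socs3 rose from 1.79 ± 0.218 to 27.8 ± 2.66 RPKM, a log2 change of 3.36 ± 0.17 (adjusted p = 1.71e-06), and Selp rose from 1.30 ± 0.157 to 13.7 ± 0.701 RPKM, a log2 change of 2.68 ± 0.17 (adjusted p = 1.17e-05). Myl10 fell from 15.5 ± 12.9 to 1.002 ± 0.214 RPKM, a log2 change of -2.79 ± 0.45 (adjusted p = 0.00133), and Tuba1b fell from 689 ± 109 to 212 ± 6.66 RPKM, a log2 change of -1.69 ± 0.12 (adjusted p = 1.98e-05). With limma, 2586 of 8553 genes were called, 1175 higher and 1411 lower, 82 of them at least 2-fold higher and 71 at least 2-fold lower, and 3667 had an unadjusted p under 0.05. The groups did not overlap for 49.9% of genes, against 10% by chance. Converting to TPM moved the median log2 change of all genes from -0.014 to 0.148 and the share of called genes that were higher from 45.4% to 74.1%.

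Further increases were Il10ra (2.65 ± 0.18, adjusted p = 1.32e-05), Cd53 (2.22 ± 0.17, adjusted p = 2.27e-05), Gadd45g (2.20 ± 0.21, adjusted p = 9.82e-05), a growth arrest gene, and the chemokine Ccl9 (2.11 ± 0.27, adjusted p = 0.000446). Further decreases were Tcf19 (-2.01 ± 0.21, adjusted p = 0.000133), the replication licensing factor Cdt1 (-1.57 ± 0.20, adjusted p = 0.000453) and the beta-tubulin Tubb4b (-1.44 ± 0.10, adjusted p = 1.49e-05). In the S phase list 39 of 45 measured members fell and 0 rose (40 and 0 adjusted over the list alone). The S phase median was -0.84 (adjusted p = 2.35e-18, alternatives from 1.27e-32 to adjusted p = 0.266 with an estimated correlation). Of its members, Mcm7 fell from 52.5 ± 5.10 to 20.6 ± 0.831 RPKM, a log2 change of -1.31 ± 0.11 (adjusted p = 3.94e-05). In the G2/M list 23 of 47 measured members fell and 1 rose (31 and 1 adjusted over the list alone). The G2/M median was -0.44 (adjusted p = 3.89e-07, alternatives from 5.29e-13 to adjusted p = 0.451 with an estimated correlation). Its called members included Cks1b (-1.13 ± 0.16, adjusted p = 0.000808). Among ribosome biogenesis and MYC target genes 29 of 43 measured members fell and 0 rose (34 and 1 adjusted over the list alone). The ribosome biogenesis median was -0.51 (adjusted p = 3.61e-11, alternatives from 2.84e-20 to adjusted p = 0.256 with an estimated correlation). Of its members, Nop56 (-0.99 ± 0.093, adjusted p = 8.66e-05) fell. In the oxidative phosphorylation list 19 of 58 measured members fell and 0 rose (21 and 0 adjusted over the list alone). The oxidative phosphorylation median was -0.21 (adjusted p = 4.86e-05, alternatives from 2.58e-09 to adjusted p = 0.581 with an estimated correlation). It was -0.043 with values rescaled to one total. The gene of cytochrome c, Cycs (-0.88 ± 0.14, adjusted p = 0.00133), fell.

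In the NF-kB list 12 of 19 measured members rose and 0 fell (15 and 0 adjusted over the list alone). The NF-kB median was 0.44 (adjusted p = 1.82e-07, alternatives from 1.22e-08 to adjusted p = 0.00908 with an estimated correlation). Of its members, Nfkb1 (0.62 ± 0.069, adjusted p = 0.00023) and Ccl4 (1.24 ± 0.16, adjusted p = 0.000442) rose. In the type I interferon list 11 of 33 measured members rose and 0 fell (11 and 0 adjusted over the list alone). The type I interferon median was 0.29 (adjusted p = 1.41e-05, alternatives from 4.73e-09 to adjusted p = 0.325 with an estimated correlation). The antiviral genes Rsad2 (0.81 ± 0.087, adjusted p = 0.00017) and Oas3 (0.68 ± 0.12, adjusted p = 0.00205) and the interferon regulator Irf7 (1.02 ± 0.16, adjusted p = 0.0014) rose. In the interferon gamma list 8 of 31 measured members rose and 4 fell (8 and 4 adjusted over the list alone). The interferon gamma median was 0.22 (adjusted p = 0.0379, alternatives from 0.00367 to adjusted p = 0.581 with an estimated correlation, not called in 4 of 11 alternatives). It was 0.094 without antibiotic replicate 1 and 0.12 without antibiotic 5-FU replicate 2. Its receptor gene Ifngr1 (0.75 ± 0.089, adjusted p = 0.000349) rose and the proteasome activator Psme2 (-0.53 ± 0.081, adjusted p = 0.00107) fell, and the list lost its call without antibiotic replicate 1 or antibiotic 5-FU replicate 2, with adjusted p = 0.191 without antibiotic replicate 1. In the fatty acid oxidation list 9 of 30 measured members rose and 2 fell (9 and 2 adjusted over the list alone). The fatty acid oxidation median was 0.14 (adjusted p = 0.0128, alternatives from 0.000617 to 0.29, adjusted p = 0.272 with an estimated correlation, not called in 2 of 11 alternatives). The rate-limiting carnitine transferase gene Cpt1a (0.46 ± 0.10, adjusted p = 0.00695) rose and Hsd17b10 (-0.51 ± 0.097, adjusted p = 0.00322) fell.

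In the HSC identity list 12 of 24 measured members rose and 3 fell (12 and 3 adjusted over the list alone). The HSC identity median was 0.38 (adjusted p = 0.000302, alternatives from 2.66e-06 to adjusted p = 0.256 with an estimated correlation). The SLAM receptor CD150, encoded by Slamf1, rose from 0.964 ± 0.211 to 2.77 ± 0.237 RPKM, a log2 change of 0.95 ± 0.091 (adjusted p = 9.82e-05), with Hoxb5 (0.85 ± 0.099, adjusted p = 0.000311) and Ly6a (1.23 ± 0.16, adjusted p = 0.000506). Among the listed quiescence regulators 6 of 14 measured members rose and 1 fell (6 and 2 adjusted over the list alone). The quiescence median was 0.36 (adjusted p = 0.0109, alternatives from 0.00162 to adjusted p = 0.216 with an estimated correlation, not called in 5 of 11 alternatives). Of its members, Hes1 (1.19 ± 0.16, adjusted p = 0.000498) and Cdkn1b (0.56 ± 0.13, adjusted p = 0.00831), which encodes p27, rose. Among the listed p53 targets 7 of 18 measured members rose and 1 fell (8 and 1 adjusted over the list alone). The p53 target median was 0.30 (adjusted p = 0.0068, alternatives from 0.000183 to adjusted p = 0.126 with an estimated correlation). Its called members included Sesn1 (0.63 ± 0.10, adjusted p = 0.00133). In the autophagy and lysosome list 8 of 25 measured members rose and 0 fell (8 and 0 adjusted over the list alone). The autophagy median was 0.26 (adjusted p = 1.61e-05, alternatives from 3.41e-07 to adjusted p = 0.126 with an estimated correlation). Its called members included Sqstm1 (0.73 ± 0.091, adjusted p = 0.000436). In the megakaryocyte and platelet list 8 of 22 measured members rose and 2 fell (9 and 2 adjusted over the list alone). The megakaryocyte median was 0.28 (adjusted p = 0.00756, alternatives from 0.000508 to adjusted p = 0.451 with an estimated correlation). Its called members included the platelet receptor gene Gp1ba (1.34 ± 0.21, adjusted p = 0.00129).

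In the lymphoid progenitor list 4 of 12 measured members rose and 0 fell (4 and 0 adjusted over the list alone). The lymphoid progenitor median was 0.14 (adjusted p = 0.0182, alternatives from 0.0135 to adjusted p = 0.451 with an estimated correlation, not called in 2 of 11 alternatives). It was 0.027 with no filter. In the myeloid progenitor list 4 of 10 measured members rose and 0 fell (4 and 0 adjusted over the list alone). The myeloid progenitor median was 0.38 (adjusted p = 0.00756, alternatives from 0.00101 to adjusted p = 0.181 with an estimated correlation). Its called members included Plac8 (1.21 ± 0.17, adjusted p = 0.000693). The list of mature neutrophil and monocyte markers was not called, with a median of -0.006 (adjusted p = 0.592), a mean of 0.13 and an upward test. S100a8 stood at 8.998 ± 2.84 RPKM without and 13.8 ± 8.50 RPKM with 5-FU. Erythroid genes had a median of 0.98 (adjusted p = 0.057), while 6 of 15 measured members rose and 2 fell (7 and 2 adjusted over the list alone). Hbb-bt rose from 34.6 ± 8.23 to 137 ± 19.8 RPKM, a log2 change of 1.97 ± 0.40 (adjusted p = 0.00455). Not called either were glycolysis, at 0.007 (adjusted p = 0.654) with a mean of -0.061 and a downward test, and immediate early genes, at 0.35 (adjusted p = 0.0888). The other uncalled lists had medians of 0.047 (adjusted p = 0.401) for iron, 0 (adjusted p = 0.884) for iron-sulfur and heme synthesis, -0.39 (adjusted p = 0.524) for MHC class II, 0.018 (adjusted p = 0.654) for antioxidant genes, -0.055 (adjusted p = 0.654) for the unfolded protein response and 0.14 (adjusted p = 0.401) for macrophage markers. The mean log2 value of the members set all 3 antibiotics 5-FU libraries apart from all 3 antibiotics libraries in each called list.

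Both comparisons of 5-FU moved largely the same genes, and they share no library. Across 8553 genes, which are not independent replicates, the log2 changes without and with antibiotics correlated at Pearson r = 0.788 (jackknife SE 0.068) and Spearman rho = 0.738, with a slope of 0.893. Of the called genes, 588 were higher and 698 lower in both. Independent lists would share 114.4 and 167.1, but these tests share each gene's variance and are not independent. Of the 3144 genes called in either, 94.9% had the same sign.

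**Figure D3:**
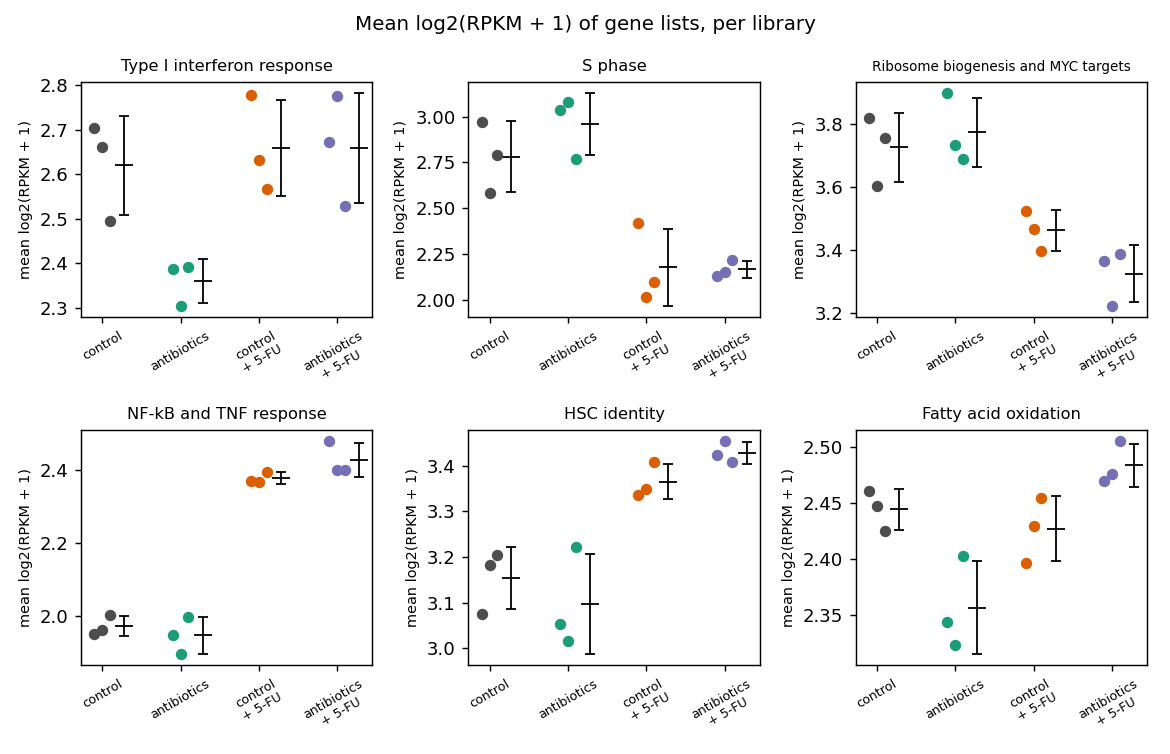
Mean log2(RPKM + 1) of the measured members of 6 gene lists in the 4 groups, with points for the 3 libraries of each group and a dash with a bar for mean ± SD. The S phase and ribosome biogenesis lists are lower and the NF-kB list higher after 5-FU in both arms, and the type I interferon list is lowest with antibiotics at steady state.

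The comparison of antibiotics with control asked how HSCs differed with antibiotics at steady state. Type I interferon genes were lower and S phase genes higher as lists, but not with an estimated correlation (adjusted p = 0.397 and 0.717). The 3 genes that rose, Rn7sk, Mir6236 and Rn18s-rs5, are annotated as non-coding RNAs. Rn7sk (chromosome 9, 78175303 to 78175633), the 7SK RNA that holds the elongation factor P-TEFb inactive, rose from 15.9 ± 2.08 to 52.3 ± 2.67 RPKM, a log2 change of 1.67 ± 0.16 (adjusted p = 0.00285). Mir6236 (chromosome 9, 110281287 to 110281409) rose from 18.0 ± 2.84 to 43.4 ± 7.63 RPKM, a log2 change of 1.23 ± 0.17 (adjusted p = 0.036). Rn18s-rs5 (chromosome 17, 39846353 to 39848827), a copy related to 18S ribosomal RNA, rose from 1376 ± 93.3 to 2126 ± 237 RPKM, a log2 change of 0.62 ± 0.091 (adjusted p = 0.0389). These libraries were also shallower in estimated depth.

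The other 3 called genes fell. The zinc finger gene Zfp513 (chromosome 5, 31198981 to 31202303) fell from 6.14 ± 0.405 to 3.76 ± 0.203 RPKM, a log2 change of -0.58 ± 0.087 (adjusted p = 0.0389). Ccdc28b (chromosome 4, 129619274 to 129623947), which is involved in the formation of cilia, fell from 5.45 ± 0.106 to 3.70 ± 0.193 RPKM, a log2 change of -0.46 ± 0.063 (adjusted p = 0.036). Gm5537 (chromosome 3, 58102996 to 58104247), a processed pseudogene named after its values were seen, fell from 11.7 ± 3.48 to 1.56 ± 1.06 RPKM, a log2 change of -2.35 ± 0.28 (adjusted p = 0.0132), and reads shared with its parent gene make its level uncertain. With limma, 6 of 8553 genes passed, 1519 had an unadjusted p under 0.05, and 22.1% of genes did not overlap, against 10% by chance. Named by the rule without passing were the linker histone gene Hist1h1d (1.25 ± 0.21, adjusted p = 0.0607) and the MHC class I gene H2-D1 (-0.40 ± 0.075, adjusted p = 0.0819). Leaving out 1 of the 12 libraries gave 1 to 25 called genes, and the i7 index as a block gave 20. Rn7sk stayed called in each of the 12 fits, but not with depth as a covariate (adjusted p = 0.181, 0.000657 to 0.181 over the alternatives). Mir6236, Rn18s-rs5, Zfp513 and Ccdc28b lost their calls in 8, 9, 8 and 9 of them, each with an adjusted p of 0.176 without antibiotic replicate 1. Over the other alternatives their adjusted p were 0.0132 to 0.231, 0.00911 to 0.253, 0.0262 to 0.252 and 0.00747 to 0.231. Gm5537 lost its call without control replicate 1, control replicate 2 or antibiotic replicate 1, with adjusted p = 0.104 without antibiotic replicate 1 and 0.00366 to 0.231 over the other alternatives.

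In the type I interferon list 0 of 33 measured members passed over all genes and 15 fell adjusted over the list alone. The type I interferon median was -0.29 (adjusted p = 2.86e-10, alternatives from 1.79e-12 to adjusted p = 0.397 with an estimated correlation). The members with the smallest p were Oasl1 (-0.45 ± 0.10, adjusted p = 0.0969), Ifi44 (-0.66 ± 0.16, adjusted p = 0.11) and Lgals3bp (-0.26 ± 0.063, adjusted p = 0.11). Lgals3bp stood at 60.9 ± 1.56 RPKM in control and 50.7 ± 1.84 RPKM with antibiotics. In the interferon gamma list 0 of 31 passed over all genes and 8 fell and 1 rose adjusted over the list alone. The interferon gamma median was -0.21 (adjusted p = 5.06e-07, alternatives from 4.97e-08 to adjusted p = 0.461 with an estimated correlation). H2-D1, a heavy chain of MHC class I, stood at 648 ± 33.7 RPKM in control and 492 ± 49.6 RPKM with antibiotics, and H2-T23 (-0.34 ± 0.090, adjusted p = 0.133) lay in the same direction, whereas Socs1 (0.89 ± 0.24, adjusted p = 0.137) lay in the other. The fatty acid oxidation list was lower, with 0 of 30 passing and 1 falling adjusted over the list alone. The fatty acid oxidation median was -0.08 (adjusted p = 0.000718, alternatives from 0.000258 to adjusted p = 0.397 with an estimated correlation). It was -0.12 without antibiotic replicate 3. Its first member was Acadvl (-0.32 ± 0.070, adjusted p = 0.0969), the very-long-chain acyl-CoA dehydrogenase. The autophagy and lysosome list was lower, with 0 of 25 passing and 3 falling adjusted over the list alone. The autophagy median was -0.14 (adjusted p = 0.00229, alternatives from 0.000625 to adjusted p = 0.397 with an estimated correlation). First by p came Hexa (-0.27 ± 0.069, adjusted p = 0.129). These 4 lists kept their calls in the 12 fits that left out 1 library. The list means set all 3 antibiotic libraries below all 3 controls for type I interferon, fatty acid oxidation and autophagy, whereas the groups overlapped for interferon gamma.

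The S phase list was higher, with 0 of 45 passing over all genes or adjusted over the list alone. The S phase median was 0.16 (adjusted p = 0.000718, alternatives from 6.84e-06 to adjusted p = 0.717 with an estimated correlation, not called in 2 of 11 alternatives). It was 0.27 without control replicate 1, 0.075 without control replicate 2 and 0.26 without antibiotic replicate 3. The G2/M list was higher too, with 0 of 47 either way. The G2/M median was 0.14 (adjusted p = 0.0157, alternatives from 0.000361 to adjusted p = 0.79 with an estimated correlation, not called in 2 of 11 alternatives). It was 0.09 without control replicate 2 and 0.054 without antibiotic replicate 2. Their first members were Hells (0.33 ± 0.10, adjusted p = 0.168), a chromatin remodeller, and Smc4 (0.30 ± 0.11, adjusted p = 0.211), a condensin subunit. Erythroid genes were lower, with 0 of 15 passing and 2 falling adjusted over the list alone. The erythroid median was -0.20 (adjusted p = 0.0135, alternatives from 0.000195 to adjusted p = 0.505 with an estimated correlation, not called in 2 of 11 alternatives). It was -0.098 without control replicate 1. The erythroid regulators Klf1 (-1.27 ± 0.26, adjusted p = 0.0846) and Gata1 (-0.67 ± 0.19, adjusted p = 0.147) came first. In the megakaryocyte and platelet list 0 of 22 passed and 3 fell adjusted over the list alone. The megakaryocyte median was -0.14 (adjusted p = 0.0323, alternatives from 0.0152 to adjusted p = 0.678 with an estimated correlation, not called in 5 of 11 alternatives). It was -0.066 without antibiotic replicate 2. First by p came Selp (-0.77 ± 0.17, adjusted p = 0.0969). Glycolysis genes were lower, with 0 of 19 either way. The glycolysis median was -0.13 (adjusted p = 0.0157, alternatives from 0.00942 to adjusted p = 0.505 with an estimated correlation, not called in 2 of 11 alternatives). It was -0.063 without antibiotic replicate 1. The unfolded protein response list was lower, with 0 of 22 passing and 2 falling and 1 rising adjusted over the list alone. The unfolded protein median was -0.094 (adjusted p = 0.0474, alternatives from 0.0106 to adjusted p = 0.678 with an estimated correlation, not called in 7 of 11 alternatives). The S phase call was lost without control replicate 2 or antibiotic replicate 2 (adjusted p = 0.138 without control replicate 2). The G2/M call was lost without control replicate 2 or antibiotic replicate 2 (adjusted p = 0.419 without antibiotic replicate 2). The erythroid call was lost without control replicate 1 or antibiotic replicate 3 (adjusted p = 0.114 without control replicate 1). The megakaryocyte call was lost without control replicate 2, antibiotic replicate 2 or antibiotic replicate 3 (adjusted p = 0.138 without control replicate 2). The glycolysis call was lost without control replicate 3 or antibiotic replicate 2 (adjusted p = 0.0581 without antibiotic replicate 2). The unfolded protein call was lost without 1 library in 5 of the 12 fits (adjusted p = 0.138 without control replicate 2). Of these 6 lists, the list means separated the groups for the unfolded protein response and overlapped for the others. The 15 other tested lists had medians from -0.33 to 0.19 and adjusted p from 0.0704 to 0.992. Among those, median, mean and test differed in sign for iron (0.029, -0.001, down), ribosome biogenesis (-0.02, 0.048, down), macrophage markers (0.19, 0.14, down) and p53 targets (0.045, 0.01, down). Neutrophil and monocyte markers had a median of -0.12 (adjusted p = 0.573), MHC class II genes -0.33 (adjusted p = 0.072) and HSC identity genes -0.066 (adjusted p = 0.191).

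The comparison of antibiotics 5-FU with control 5-FU asked how regenerating HSCs differed with antibiotics. Rn7sk rose again, from 18.0 ± 4.25 to 44.2 ± 5.33 RPKM, a log2 change of 1.27 ± 0.16 (adjusted p = 0.009), and so did Rn18s-rs5, from 1062 ± 98.3 to 2008 ± 48.6 RPKM, a log2 change of 0.92 ± 0.091 (adjusted p = 0.00206). Serpinf1 rose from 2.19 ± 0.0582 to 5.11 ± 0.532 RPKM, a log2 change of 0.94 ± 0.097 (adjusted p = 0.00229). Ebi3 (chromosome 17, 55952623 to 55957021), a subunit shared by interleukins 27 and 35, rose from 8.73 ± 1.31 to 18.2 ± 2.19 RPKM, a log2 change of 0.99 ± 0.13 (adjusted p = 0.0111). Polr2a (chromosome 11, 69733997 to 69758637), the largest subunit of RNA polymerase II, rose from 6.08 ± 0.147 to 8.39 ± 0.350 RPKM, a log2 change of 0.41 ± 0.064 (adjusted p = 0.0441). Ribosome biogenesis genes and mature neutrophil markers were lower as lists, but not with an estimated correlation (adjusted p = 0.897 for each). All 10 splits of these libraries called at least 3 lists. The marker S100a8 stood at 21.4, 57.7 and 143 RPKM in control 5-FU and 8.32, 9.44 and 23.6 RPKM in antibiotics 5-FU libraries. The abundant Lyz2 stood at 97.7 to 126 and 98.4 to 106 RPKM.

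Of the 4 genes that fell, 3 met the naming rule. Smim5 (chromosome 11, 115899966 to 115906269), a small membrane protein, fell from 7.01 ± 0.474 to 4.26 ± 0.172 RPKM, a log2 change of -0.61 ± 0.087 (adjusted p = 0.0242). Brat1 (chromosome 5, 140705011 to 140719379), which binds BRCA1 and ATM, fell from 7.83 ± 0.479 to 5.11 ± 0.506 RPKM, a log2 change of -0.53 ± 0.083 (adjusted p = 0.0441), and Tomm34 (chromosome 2, 164053540 to 164071169), a co-chaperone of mitochondrial import, fell from 5.69 ± 0.325 to 4.03 ± 0.135 RPKM, a log2 change of -0.41 ± 0.066 (adjusted p = 0.049). Snn (chromosome 16, 11066298 to 11074983), which encodes stannin, rose from 2.70 ± 0.297 to 4.99 ± 0.418 RPKM, a log2 change of 0.70 ± 0.076 (adjusted p = 0.00315), and Gm37599 (chromosome 1, 141356789 to 141357277), a transcript of unknown coding status, fell from 3.28 ± 0.209 to 1.37 ± 0.107 RPKM, a log2 change of -0.85 ± 0.078 (adjusted p = 0.00206). The beta-actin gene Actb was named by the rule without passing (log2 change -0.68 ± 0.11, adjusted p = 0.0553). With limma, 10 of 8553 genes passed, 6 higher and 4 lower, 1275 had an unadjusted p under 0.05, and 21.2% did not overlap, against 10% by chance. The count was 47 with values converted to TPM, of which 44.7% were higher, and 22 with the i7 index as a block. It was 6 to 28 on leaving out 1 library. Serpinf1, Rn18s-rs5, Snn and Gm37599 stayed called in the 12 fits that left out 1 library, and Snn was not called with 2 groups only. Rn7sk lost its call without antibiotic 5-FU replicate 1 (adjusted p = 0.0543, 0.00256 to 0.156 over the other alternatives). Ebi3 lost its call without antibiotic 5-FU replicate 2 (adjusted p = 0.0626, 0.00463 to 0.116 over the other alternatives). Polr2a, Tomm34, Brat1 and Smim5 lost theirs in 11, 11, 8 and 4 fits, with adjusted p of up to 0.151, 0.159, 0.159 and 0.128. Over the other alternatives theirs were 0.0192 to 0.156, 0.0192 to 0.158, 0.012 to 0.156 and 0.00873 to 0.116.

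Among ribosome biogenesis and MYC target genes 0 of 43 measured members passed over all genes and 7 fell adjusted over the list alone. The ribosome biogenesis median was -0.14 (adjusted p = 4.66e-07, alternatives from 8.75e-10 to adjusted p = 0.897 with an estimated correlation). The members with the smallest p were Nop2 (-0.45 ± 0.10, adjusted p = 0.0901) and Ddx21 (-0.46 ± 0.10, adjusted p = 0.0901), and the list means did not overlap. Among the listed mature neutrophil and monocyte markers 0 of 7 passed and 4 fell adjusted over the list alone. The neutrophil marker median was -1.60 (adjusted p = 0.00435, alternatives from 1.03e-05 to adjusted p = 0.897 with an estimated correlation). It was -0.97 without control 5-FU replicate 3 and -0.27 with no filter. The list means of the groups overlapped, but were lower with antibiotics within each i7 index. S100a8 stood at 74.1 ± 62.6 and 13.8 ± 8.50 RPKM (log2 change -2.10 ± 0.58, adjusted p = 0.133), and Ngp at 20.1 ± 24.4 and 1.29 ± 1.07 RPKM (log2 change -2.58 ± 0.72, adjusted p = 0.136). In the megakaryocyte and platelet list 0 of 22 passed and 2 fell adjusted over the list alone. The megakaryocyte median was -0.12 (adjusted p = 0.0287, alternatives from 0.0287 to adjusted p = 0.897 with an estimated correlation, not called in 5 of 11 alternatives). It was -0.019 without control 5-FU replicate 1, -0.21 without control 5-FU replicate 2 and -0.19 without control 5-FU replicate 3. The call was lost without control 5-FU replicate 1 (adjusted p = 0.578). Its integrin gene Itgb3 (-0.78 ± 0.20, adjusted p = 0.11) came first. The other 22 tested lists had medians from -0.20 to 0.16 and adjusted p from 0.102 to 0.754. Type I interferon genes had a median of -0.026 (adjusted p = 0.754), S phase genes 0.019 (adjusted p = 0.707) and fatty acid oxidation genes 0.074 (adjusted p = 0.272). Among the uncalled lists, median and mean differed in sign for S phase, glycolysis, immediate early and myeloid progenitor genes, and the test pointed down against a positive median and mean for interferon gamma and erythroid genes.

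**Figure D4:**
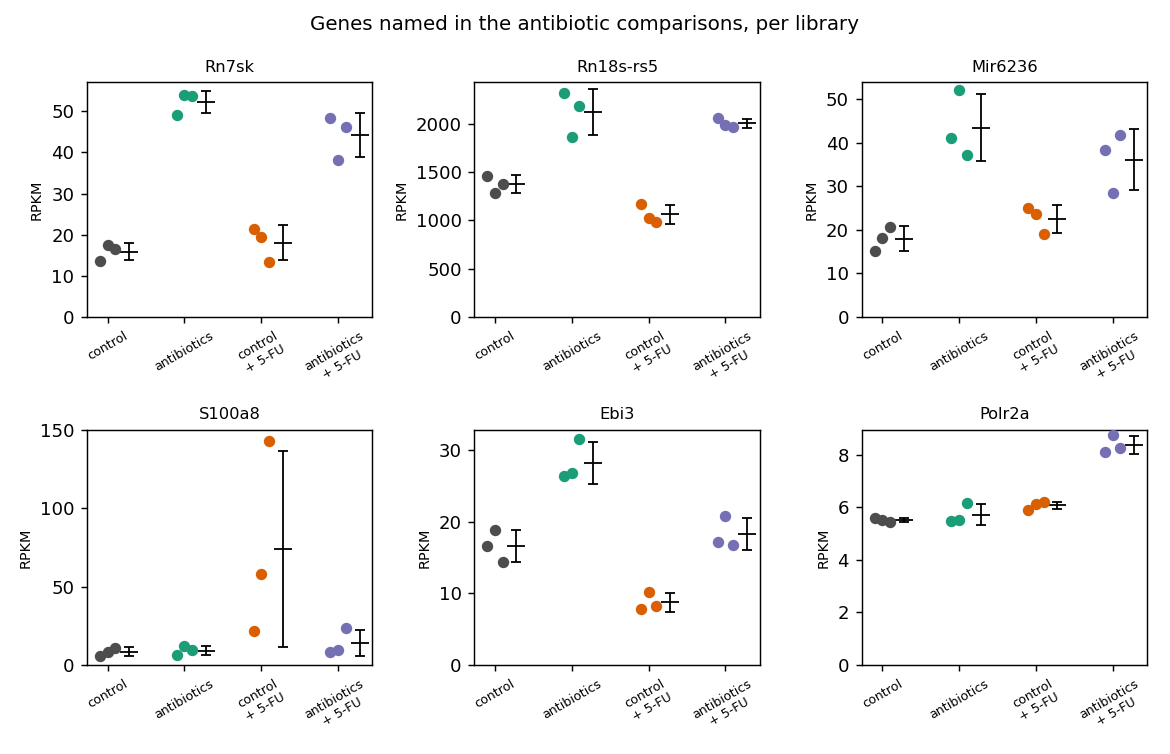
RPKM of Rn7sk, Rn18s-rs5, Mir6236, S100a8, Ebi3 and Polr2a in the 4 groups, with points for the 3 libraries of each group and a dash with a bar for mean ± SD. Rn7sk and Rn18s-rs5 are higher with antibiotics at steady state and after 5-FU, and S100a8 is spread from 21.4 to 143 RPKM in the control 5-FU libraries.

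The antibiotic changes at steady state and after 5-FU, which share no library, correlated across genes at Pearson r = 0.39 (jackknife SE 0.13) and Spearman rho = 0.366. Rn7sk and Rn18s-rs5 were the 2 genes called higher in both, and 0 genes were called lower in both.

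The interaction asked whether the change after 5-FU differed between mice with and without antibiotics. With antibiotics the change was more positive for type I interferon and fatty acid oxidation genes and more negative for S phase and ribosome biogenesis genes. None of these lists passed with an estimated correlation (adjusted p = 0.55, 0.221, 0.698 and 0.55). With limma, 1 of 8553 genes passed and 710 had an unadjusted p under 0.05. That gene, Gm37599, named after its values were seen, had an interaction of -1.004 ± 0.11 (adjusted p = 0.0134), with 3.11 ± 0.321 and 3.28 ± 0.209 RPKM without antibiotics and 3.56 ± 0.268 and 1.37 ± 0.107 RPKM with antibiotics. It was not called with the i7 index as a block, where 0 genes were, nor in 7 of the 12 fits that left out 1 library, with adjusted p = 0.0789 without antibiotic 5-FU replicate 3 and 0.00376 to 0.111 over the other alternatives. Zfp513 (0.75 ± 0.12, adjusted p = 0.272), H1f0 (0.80 ± 0.14, adjusted p = 0.361) and Serpinf1 (0.75 ± 0.14, adjusted p = 0.374) had the smallest p among positive values, and Sssca1 (-0.50 ± 0.10, adjusted p = 0.5) and Actg1 (-0.51 ± 0.11, adjusted p = 0.5) among negative values, without passing.

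Of the 25 lists, 8 passed the interaction test, with 0 members passing over all genes or adjusted over the list alone in any of these. The type I interferon median was 0.25 (adjusted p = 9.32e-09, alternatives from 1.09e-09 to adjusted p = 0.55 with an estimated correlation). The interferon gamma median was 0.21 (adjusted p = 0.000111, alternatives from 8.36e-05 to adjusted p = 0.55 with an estimated correlation). The fatty acid oxidation median was 0.16 (adjusted p = 7.88e-06, alternatives from 2.28e-06 to adjusted p = 0.221 with an estimated correlation). The HSC identity median was 0.14 (adjusted p = 0.0147, alternatives from 0.00353 to adjusted p = 0.55 with an estimated correlation, not called in 2 of 10 alternatives). It was 0.08 without antibiotic replicate 2. The erythroid median was 0.25 (adjusted p = 0.041, alternatives from 0.000171 to adjusted p = 0.55 with an estimated correlation, not called in 4 of 10 alternatives). The S phase median was -0.21 (adjusted p = 0.00019, alternatives from 2.24e-05 to adjusted p = 0.698 with an estimated correlation). It was -0.11 without control replicate 2, -0.081 without control 5-FU replicate 1 and -0.13 without antibiotic replicate 2. The ribosome biogenesis median was -0.18 (adjusted p = 4.56e-05, alternatives from 1.26e-06 to adjusted p = 0.55 with an estimated correlation). The neutrophil marker median was -1.49 (adjusted p = 0.0379, alternatives from 0.00824 to adjusted p = 0.55 with an estimated correlation). It was -0.85 without control 5-FU replicate 3 and -0.20 with no filter. The members with the smallest p were Rsad2 for type I interferon (0.41 ± 0.12, adjusted p = 0.505), Acadm for fatty acid oxidation (0.43 ± 0.15, adjusted p = 0.554), Slamf1 for HSC identity (0.46 ± 0.13, adjusted p = 0.505), Mcm7 for S phase (-0.34 ± 0.16, adjusted p = 0.598) and Ddx21 for ribosome biogenesis (-0.57 ± 0.15, adjusted p = 0.505). Calls were lost without control 5-FU replicate 1 for S phase (adjusted p = 0.139), without control replicate 2, control 5-FU replicate 1 or antibiotic replicate 2 for HSC identity (up to 0.0759), without 4 libraries for erythroid genes (up to 0.227, without control replicate 1) and without 7 libraries for neutrophil markers (up to 0.232, without control replicate 1). The 17 other lists had medians from -0.07 to 0.22 and adjusted p from 0.0541 to 0.958, among which median, mean and test differed in sign for the unfolded protein response, myeloid progenitor, lymphoid progenitor and macrophage lists.

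The 8 genes that had been chosen to be reported in every comparison were measured as follows, with values in the order control, antibiotics, control 5-FU and antibiotics 5-FU. The proliferation marker Mki67 stood at 3.41 ± 0.288, 4.30 ± 1.26, 2.03 ± 0.580 and 2.45 ± 0.405 RPKM and fell after 5-FU, by 0.56 without antibiotics (adjusted p = 0.0493) and by 0.59 with antibiotics (adjusted p = 0.0303) on the log2 scale. Without antibiotics the call was lost in 9 of the 12 fits that left out 1 library, with adjusted p = 0.153 without control 5-FU replicate 2 and 0.00596 to 0.155 over the other alternatives. With antibiotics it was lost in 5, with adjusted p = 0.11 without antibiotic replicate 2 and 0.00906 to 0.105 over the other alternatives. Procr, which encodes the HSC marker EPCR, stood at 19.7 ± 2.25, 18.5 ± 3.36, 25.2 ± 4.39 and 30.6 ± 1.19 RPKM, rose after 5-FU with antibiotics (log2 change 0.71 ± 0.14, adjusted p = 0.00453) and had a log2 change of 0.33 ± 0.14 without antibiotics (adjusted p = 0.122), with an interaction of 0.38 ± 0.20 (adjusted p = 0.651). The HSC transcription factor gene Hlf stood at 5.84 ± 0.310, 7.42 ± 0.321, 6.63 ± 1.87 and 7.59 ± 0.312 RPKM, the ferritin gene Fth1 at 501 ± 30.9, 515 ± 45.0, 426 ± 40.5 and 462 ± 20.9 RPKM, the iron exporter gene Slc40a1 at 1.55 ± 0.5005, 1.48 ± 0.845, 1.75 ± 0.797 and 1.43 ± 0.156 RPKM and the cell cycle inhibitor gene Cdkn1a at 0.333 ± 0.0236, 0.555 ± 0.0270, 1.93 ± 2.53 and 1.46 ± 0.820 RPKM, and none of these 4 passed in any comparison. The smallest adjusted p were 0.309 for Hlf, 0.0779 for Fth1, 0.811 for Slc40a1 and 0.198 for Cdkn1a. The transferrin receptor gene Tfrc, with means of 0.628, 0.588, 0.536 and 0.723 RPKM, and Mecom, with 0.307, 0.348, 0.420 and 0.514 RPKM, lay below the filter and were not tested.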

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

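The tests of mature immune cells and of 1 control 5-FU library were chosen only after the result was seen. The interaction was tested for all 25 lists, and 9 results, 1 gene and 8 lists, differed in their 5-FU change between mice with and without antibiotics. With an estimated correlation 0 lists did.

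The median interaction was 0.251 for the type I interferon list (adjusted p = 9.32e-09) and 0.213 for the interferon gamma list (adjusted p = 0.000111), which follow from lower values with antibiotics at steady state. Leaving out each of the 6 steady-state libraries kept the type I interferon median between -0.338 and -0.256, which argues against 1 library as the source. With protein-coding genes alone, rescaled to one total, it was -0.301, which argues against reads taken by ribosomal RNA and pseudogenes. Fewer mature immune cells in the sort, whose gates are not given, stay open as a source. Outside the interferon lists 21 markers went both ways, with quartiles of -0.116 and 0.207 and a median of 0.048. Depth, which separated the steady-state groups, was not tested for lists and stays open.

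The mature neutrophil and monocyte list had a median interaction of -1.485 (adjusted p = 0.0379). Neutrophil RNA in 1 control 5-FU library was tested as a source: over the 6 fits that left out 1 library, the median change with antibiotics after 5-FU lay between -2.133 and -0.966, which argues against it. RNA of neutrophils in several control 5-FU libraries may be a source and was not tested apart from this, with S100a8 at 21.4, 57.7 and 143 RPKM there and Lyz2 at 97.7 to 126 RPKM. None of the 7 measured members is in another list.

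The fatty acid oxidation list had an interaction of 0.157 (adjusted p = 7.88e-06), HSC identity one of 0.137 (adjusted p = 0.0147) and the erythroid list one of 0.251 (adjusted p = 0.041). The S phase list had one of -0.213 (adjusted p = 0.00019) and ribosome biogenesis one of -0.18 (adjusted p = 4.56e-05). Gm37599 had one of -1.004 (adjusted p = 0.0134). Chance could not be excluded for the interaction: 12 of 100 splits of the libraries called at least 1 gene, as the real one did, and 39 of 100 called at least 8 lists. The highest other counts were 204 genes and 14 lists. Splits can carry antibiotic effects of both arms, so the shares cannot decide on chance.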

How the results depend on the processing

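One total, protein-coding genes alone and the depth covariate came after the data were seen. As the labels give no replicate numbers, libraries were paired only by i7 index, a technical label, in the i7 block. Fitting 2 groups only gives no interaction, and the i7 block applies only to the antibiotic comparisons and the interaction. Lists were not run with the i7 block or depth covariate, nor correlations with these, 2 groups only or robust moderation. Gm37599 was absent from the 5 RPKM and protein-coding fits, and Rn7sk, Mir6236, Rn18s-rs5 and Gm5537 from the latter. Other causes were not tested. For antibiotics at steady state the 6 called genes became 11 with no filter, 15 with a filter at 5 RPKM, 13 as TPM, 49 with library weights, 20 with the i7 block, 12 at one total, and 0 with protein-coding genes alone or the depth covariate, where limma was used throughout and 1519 genes had an unadjusted p under 0.05 at first. Leaving out 1 library gave 25 without antibiotic replicate 3, 22 without control 5-FU replicate 1, 10 without control 5-FU replicate 3, 3 without antibiotic 5-FU replicate 1 or 2, 2 without control replicate 1 or 3, control 5-FU replicate 2 or antibiotic 5-FU replicate 3, and 1 without control replicate 2 or antibiotic replicate 1. For 5-FU without antibiotics the 1846 genes became 1184 with a filter at 5 RPKM and 812 with 2 groups only, and 941 to 2080 on leaving out 1 library, with 941 without control replicate 3 and 995 without control 5-FU replicate 3. For 5-FU with antibiotics the 2586 genes became 1460 with a filter at 5 RPKM, and 1620 to 2879 on leaving out 1 library, with 1620 without antibiotic replicate 2 and 1651 without antibiotic 5-FU replicate 2. For antibiotics after 5-FU the 10 genes became 22 with a filter at 5 RPKM, 47 as TPM, 72 with quantile normalization, 120 with library weights, 22 with the i7 block, 3 with 2 groups only, 51 at one total, 23 with protein-coding genes alone and 40 with the depth covariate. They became 28 without control 5-FU replicate 3, 25 without control 5-FU replicate 1 and 6 without antibiotic 5-FU replicate 1 or 2. For the interaction the 1 gene became 7 with no filter and 0 with a filter at 5 RPKM, the i7 block, protein-coding genes alone or the depth covariate, with limma and 710 genes at an unadjusted p under 0.05 at first. It became 3 without antibiotic replicate 3 and 0 without control replicate 2 or 3, control 5-FU replicate 2, antibiotic replicate 1 or 2 or antibiotic 5-FU replicate 2 or 3. An estimated correlation left 0 of the 10 lists for antibiotics at steady state, 1 of 15 for 5-FU without and 1 of 15 with antibiotics, 0 of 3 for antibiotics after 5-FU and 0 of 8 for the interaction. Leaving out 1 library gave 5 to 12 lists for antibiotics at steady state, 5 without antibiotic replicate 2 and 6 without control replicate 2, and 3 to 5 after 5-FU, 5 without control 5-FU replicate 2 or antibiotic 5-FU replicate 2. After 5-FU the 3 lists became 6 with no filter, 1 with a filter at 5 RPKM and 5 with protein-coding genes alone, and for the interaction 8 became 5 with a filter at 5 RPKM. The share of called genes that were higher at one total was 81.2% and 74.1% for 5-FU without and with antibiotics, and as TPM 38.5% for antibiotics at steady state. No called change of a named gene turned sign, and the correlations stayed within 0.735 to 0.82 for 5-FU and 0.297 to 0.442 for antibiotics. Signs of uncalled genes turned as follows. At steady state the depth covariate gave 0.269 for Procr, -0.189 for Mki67 and -0.838 for Cdkn1a, and leaving out 1 library gave -0.006 to 0.111 for Fth1, -0.335 to 0.094 for Slc40a1 and -0.228 to 0.003 for Procr. For 5-FU without antibiotics Fth1 was 0.038 with quantile normalization, Col1a2 0.126 as TPM, 0.051 at one total and 0.009 with protein-coding genes alone, Lmo4 0.008 as TPM and 0.005 at one total, and Slc40a1 -0.124 with library weights and -0.125 with the depth covariate. Leaving out 1 library gave -0.02 to 0.297 for Spic, -0.535 to 0.276 for Cxcl12, -0.202 to 0.116 for Col1a2 and -0.131 to 0.252 for Slc40a1. For 5-FU with antibiotics Lmo4 was 0.152 as TPM, 0.03 with library weights, 0.099 at one total and 0.058 with protein-coding genes alone, Fth1 0.021 as TPM, 0.08 with quantile normalization and 0.021 at one total, Slc40a1 -0.018 with quantile normalization and -0.092 with library weights, and Hlf -0.032 with the depth covariate. Leaving out 1 library gave -0.106 to 0.547 for S100a9, -0.022 to 0.068 for Srgn, -0.104 to 0.043 for Lmo4, -0.145 to 0.285 for Slc40a1 and 0 to 0.06 for Hlf. For antibiotics after 5-FU Cdkn1a was -0.029 with quantile normalization and -0.283 with the depth covariate, and leaving out 1 library gave -0.302 to 0.081 for Slc40a1, -0.02 to 0.321 for Hlf and -0.35 to 0.175 for Cdkn1a. For the interaction the depth covariate gave -0.033 for Fth1, 0.214 for Slc40a1, 0.261 for Mki67 and 0.555 for Cdkn1a, library weights gave 0.031, 0.033 and 0.138 for Slc40a1, Mki67 and Cdkn1a, and a pseudocount of 0.1 gave 0.001 for Mki67. Leaving out 1 library gave -0.237 to 0.192 for Slc40a1, -0.32 to 0.021 for Hlf and -0.252 to 0.095 for Mki67.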

Other observations

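Histone genes, 38 of them measured, had a median log2 change of 0.416 with antibiotics at steady state, with 25 positive, and of 0.04 after 5-FU. Small structured RNAs, 14 of them, had medians of 0.174 and -0.028. These classes were formed after the data had been seen.

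For the non-coding RNAs higher with antibiotics, the tests on S phase, depth after 5-FU and carry-over at steady state, and a condition on carry-over, were chosen only after the result was seen. Carry-over of RNA without a poly(A) tail could raise Rn7sk, Rn18s-rs5 and Mir6236, but the 46 other histone and small RNA members had a median of -0.026 after 5-FU, which argues against carry-over of the whole class there. At steady state their median was 0.219, with 31 of 46 positive, and carry-over stays open. With depth as a covariate the 3 RNAs kept at least 97.0% of their change after 5-FU, Rn7sk at 1.267 ± 0.171 (SE, adjusted p = 0.0191). This argues against depth as the whole source there, where Mir6236 was not called (0.651, adjusted p = 0.121 without depth). At steady state depth and antibiotics cannot be told apart, as the libraries did not overlap in depth: Rn7sk went from 1.668 ± 0.158 to 1.66 ± 0.228, and the wider SE ended its call (adjusted p = 0.181). The upper quartile of the S phase list was 0.064 after 5-FU, against changes of 1.269 for Rn7sk and 0.922 for Rn18s-rs5, which argues against more cells in S phase there. At steady state it was 0.251, against 1.668 and 0.623, which argues against it as the whole source too.

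For the pairwise comparisons the 10 splits of 6 libraries are too few for a share under 0.05. The real split and the highest other called 6 and 1 genes for antibiotics at steady state, 1846 and 0 for 5-FU without antibiotics, 2586 and 0 for 5-FU with antibiotics, and 10 and 1 for antibiotics after 5-FU. In each, only the real split of the 10 reached its count. For lists the real split and the highest other called 10 and 11, 15 and 13, 15 and 13, and 3 and 9 in the same order. The real list count was reached in 2, 1, 1 and 10 of 10 splits. For both antibiotic comparisons another split called more lists.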
